A study of Rattus norvegicus with 12 samples.

How the data were processed

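Total RNA from rat kidneys and recombined tissue was labelled as biotinylated cRNA by the standard Affymetrix protocol, per the labels' protocols. The authors' deposited values are probe set intensity values on a linear scale, made with GCOS per the submitters' processing notes; its version, algorithm and settings are not given in the sources used here. The deposited values ran from 0.447 to 318614. The mean of each array without its lowest and highest 2% of values was 2499.9 on all 12 arrays, so a global scaling of each array had been applied. Such scaling sets each array's mean equal, and a change of total RNA per cell would not show. No detection calls were used, and a low signal has no bound of its own here.

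Each of the 12 columns was matched to its sample, and the groups were E13 (n = 3), E18 (n = 4), Wk4 (n = 3) and recombined (n = 2). No pair of arrays held identical values. The 57 control probe sets were left out of all tests. Values were used as log2(signal + 271), where 271 is the 25th percentile of all values, which draws in the differences of dim probe sets. The array medians on this scale spanned 0.27, under the limit set for further normalization, so the deposited scaling was kept. Probe sets above their array's 40th percentile on at least 2 arrays were kept, which left 22599 and removed 8443.

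Gene names came from the platform annotation given with the data. Of the 31042 probe sets, 20826 had 1 symbol, 436 several and 9780 none, and no gene was named from a probe set with several. By gene ID, 20758 of the symbols matched the current rat annotation. Genes with more than 1 kept probe set, 3451 of 11920, were represented by the probe set with the highest mean. No coordinates are given, since no genome build is named for the deposited values.

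All 12 arrays entered a single linear model in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, which shares the spread over the groups, with 8 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the kept probe sets. A call needed an adjusted p under 0.05 and a change of at least 3-fold, the fold named in the study's design. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 95 tests (19 lists in 5 comparisons), and again with a correlation estimated per list. With the estimated correlation 15 of the 57 list calls were kept; wherever a list named in the text lost its call, that p is given. The count of called genes adjusted over the list alone was the same as that over all probe sets in all 95 tests. The lists were those for ureteric bud tip, collecting duct and ureteric stalk, nephron progenitor, early nephron, podocyte, proximal tubule, loop of Henle and distal tubule, endothelial, renal stroma, extracellular matrix and myofibroblast, leukocyte, erythroid, cell cycle, neural and Schwann, skeletal muscle and cartilage, hypoxia and glycolysis, tubular injury, fatty acid oxidation and mitochondrial metabolism, and urothelium and basal epithelium. They held 393 measured genes, 6 of them in more than 1 list. The macrophage, lymphocyte, MHC class II, smooth muscle, imprinted and further hypoxia lists were added later. Their tests in the same 5 comparisons were adjusted among themselves, apart from the 95.

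The groups, tests, lists and the rule for named genes were fixed before the data were examined. Per comparison, the rule took the 5 highest and 5 lowest called genes with a single symbol, not an unnamed clone, whose arrays did not overlap between the groups, and the 2 members of each list with the largest change. Other list members served only as examples with their values. The position of an array between stages is the slope, through the origin, of its difference from the E13 mean on the difference between the stage means.

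The steps were first tested on simulated arrays, in which 200 probe sets were changed by known folds. For recombined tissue against E13, with 21868 probe sets tested, 64% of those changed by 4-fold and 98% of those changed by 8-fold were called, 2% of those changed by 2-fold, and 4 unchanged probe sets. For E18 against E13 the shares at 4-fold and 8-fold were 70% and 98% over 21812 probe sets, and for Wk4 against E13 64% and 98% over 21782. In a simulated list test of recombined tissue against E13, the 1 shifted list of 19 passed and 0 of the others did. Its probe sets varied independently, so it does not cover lists whose members move together.

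Alternatives covered the pseudocount (none, and 4 times as large), quantile normalization, median centring, no filter or a 60th percentile filter, each array left out in turn, the replicate number as a block, the variance model, only the arrays compared, and 2-fold or fold-only calls. For the lists they were the estimated correlation, fry, and the mean of a gene's probe sets. Sets of embryonic arrays, found from the residuals, were added after the data were seen; set 1 holds 1 E13 array and set 2 holds 1 E18 array. Figures were drawn with matplotlib in Python.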

Results

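RNA from rat kidney and from a cultured kidney tissue was measured on 12 Affymetrix arrays, each read out as a signal for 31042 probe sets besides 57 control probe sets. Kidneys were taken at embryonic day 13 (E13, n = 3), at embryonic day 18 (E18, n = 4) and 4 weeks after birth (Wk4, n = 3). The remaining group (n = 2), called recombined tissue here, joined UBs that had formed in culture and had not branched with MM, and was cultured for 6 days. In kidney development these abbreviations stand for the ureteric bud, the epithelial outgrowth that makes the collecting ducts, and the metanephric mesenchyme, which makes the nephrons. The design asked whether tissue built this way goes through the steps of the kidney in vivo, with a 3-fold difference between any of the 4 conditions as its measure of change. The median signal of the arrays lay between 799 and 1020, and the number of arrays limits the precision of each value. The labels do not say whether replicates came from separate animals, litters or cultures, so the p-values measure the spread between these samples, which may be technical. Only E18 replicate 2 was told apart from the other arrays of its stage by sex, as described further on. Below, a level is the mean deposited signal ± SD, a difference is on the log2(signal + 271) scale ± SE, and adjusted p-values come from limma. A probe set was called when its adjusted p was under 0.05 and its change at least 3-fold.

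The step from E13 to E18 asked what changes while the embryonic kidney forms its first nephrons. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, went from 141 ± 64.2 (SD, n = 3) to 15991 ± 2042 (SD, n = 4), a difference of 5.31 ± 0.16 (limma adjusted p = 4.63e-11). Fxyd2, a regulator of the sodium pump, rose by 4.60 ± 0.18, the amino acid transporter gene Slc7a13 by 4.42 ± 0.16 and Pdzk1, a scaffold of brush border transporters, by 4.41 ± 0.15. The largest decreases among named genes were those of the embryonic globins Hbz, which dropped from 112720 ± 18230 to 1835 ± 769 (difference -5.81 ± 0.24, adjusted p = 7.22e-10), and Hbg1 (-4.66 ± 0.23), while the adult globin Hbb rose by 4.57 ± 0.11. Fndc3c1 (-3.66 ± 0.22), Isl1 (-3.54 ± 0.38), a homeobox gene, and the opioid receptor gene Oprk1 (-3.24 ± 0.23) also fell.

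Of 35 measured proximal tubule genes, 21 rose from E13 to E18 and 0 fell, with the same 21 as the count adjusted over the list alone (camera adjusted p = 3.74e-23). Hnf4a, a transcription factor of the proximal tubule, rose from 35.6 ± 14.0 to 4821 ± 870. Of 24 collecting duct and ureteric stalk genes, 15 rose (adjusted p = 2.33e-13), among them the water channel gene Aqp2 (4.07 ± 0.37) and Tfcp2l1 (3.29 ± 0.23). The loop of Henle and distal tubule list held 6 risers of 20 (adjusted p = 4.06e-09). Of 22 early nephron genes, 8 rose, with Irx1 (2.95 ± 0.15) and Pax8 (2.56 ± 0.28) ahead, and 1 fell (adjusted p = 2.49e-06, but adjusted p = 0.0518 with an estimated correlation). Of 18 podocyte genes 3 rose, including the slit diaphragm gene Nphs1 (3.05 ± 0.27; adjusted p = 6.59e-05, and adjusted p = 0.0911 with an estimated correlation). The extracellular matrix and myofibroblast list had 5 of 25 genes higher, led by the collagen gene Col6a3 (3.36 ± 0.14) and Tnc (2.94 ± 0.27), with adjusted p = 3.51e-06 for the list and adjusted p = 0.24 with an estimated correlation. Of 17 nephron progenitor genes 0 were called by limma (camera adjusted p = 0.457), although 8 had an adjusted p under 0.05 at a smaller change, and 1 was called lower without E13 replicate 1. Their median difference was 0.09 and their mean -0.01, while the test pointed down; the widest differences were those of Meox1 (-1.35 ± 0.18) and Crym (1.32 ± 0.18). Of 34 cell cycle genes limma called 0, and 7 had an adjusted p under 0.05, all with lower values at E18 (camera adjusted p = 0.000314, and adjusted p = 0.465 with an estimated correlation). In the erythroid list 4 of 13 genes fell, or 2 without E18 replicate 2, and 1 rose; its median was 0.17, its mean -0.52 and its test pointed down (adjusted p = 0.282). The renal stroma list had a median of -0.06 and a mean of 0.05, and its test pointed down (adjusted p = 0.332).

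Smaller shifts were found in other lists between E13 and E18. The fatty acid oxidation list had 2 of 26 genes higher (camera adjusted p = 2.15e-06). Tubular injury genes were higher in 4 of 19 cases (adjusted p = 0.000452, and adjusted p = 0.201 with an estimated correlation) and ureteric bud tip genes in 2 of 10 (adjusted p = 0.0373, and adjusted p = 0.295 with an estimated correlation). The leukocyte list had 1 of 23 genes higher, or 2 without E13 replicate 1 (adjusted p = 9.36e-05, and adjusted p = 0.295 with an estimated correlation). Lower at E18 in the neural and Schwann list was 1 of 19 genes, or 2 without E13 replicate 2 (adjusted p = 0.00382, and adjusted p = 0.295 with an estimated correlation).

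In all, 529 of 22599 probe sets were called between E13 and E18, 437 higher and 92 lower at E18. The embryonic arrays fell into 2 sets across stages, described further on, and with the set as a covariate the count was 531. Within set 1 (E13 replicate 1 with E18 replicates 1 to 3) it was 591, and within set 2 (E13 replicates 2 and 3 with E18 replicate 4) it was 503. In each set a stage had a single array, E13 replicate 1 or E18 replicate 4, and its spread was taken from the other groups, so these counts do not test the step within a set.

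The step from E18 to Wk4 covered the passage from the growing to the mature kidney. Kap, an androgen-regulated protein of the proximal tubule, went from 43.4 ± 13.8 (SD, n = 4) to 192360 ± 21930 (SD, n = 3), a difference of 9.25 ± 0.14 (limma adjusted p = 1.56e-14). Umod, which encodes the main protein of normal urine, rose by 8.08 ± 0.22, Sult1c2a by 8.32 ± 0.30, Cyp4a8 by 7.09 ± 0.16 and Egf by 6.81 ± 0.19. Lower at Wk4 were the embryonic globin Hbe1 (-6.70 ± 0.27), the imprinted growth-related genes Mest (-5.64 ± 0.27), Igf2 (-5.57 ± 0.19) and H19 (-5.53 ± 0.23), and Shisa3 (-5.08 ± 0.17).

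Nearly the whole proximal tubule list rose between E18 and Wk4: 34 of 35 genes were called higher (camera adjusted p = 4.3e-23), led by Acy3 (5.86 ± 0.17) and the organic cation transporter gene Slc22a2 (5.79 ± 0.23). The loop of Henle and distal tubule list rose in 14 of 20 genes (adjusted p = 6.88e-10). Of 24 collecting duct genes, 12 rose, among them the proton pump subunit gene Atp6v1g3 (4.09 ± 0.25; adjusted p = 9.75e-07, and adjusted p = 0.0874 with an estimated correlation). In the fatty acid oxidation and mitochondrial metabolism list 7 of 26 genes rose by at least 3-fold and 25 had an adjusted p under 0.05 with higher values at Wk4 (adjusted p = 9.26e-12); Acsm2 (5.43 ± 0.25) and Acsm3 (4.83 ± 0.20), which activate medium-chain fatty acids, changed most. Cell cycle genes fell in 32 of 34 cases, with Ttk (-4.38 ± 0.22) and Bub1b (-4.22 ± 0.20), both spindle checkpoint kinases, lowest (adjusted p = 2.94e-15, and adjusted p = 0.153 with an estimated correlation).

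Of 17 nephron progenitor genes 9 fell, including Uncx (-3.28 ± 0.34) and Wt1 (-2.79 ± 0.15), and 2 rose, or 1 without Wk4 replicate 1 (camera adjusted p = 0.0105, and adjusted p = 0.28 with an estimated correlation). The ureteric bud tip list fell in 5 of 10 genes, with Etv4 (-3.67 ± 0.39) and the receptor gene Ret (-3.35 ± 0.16) ahead (adjusted p = 0.00202, and adjusted p = 0.188 with an estimated correlation). Against E18 replicate 4 alone (n = 1), with the spread taken from the other groups, only 3 of these 10 genes were called. Renal stroma genes fell in 7 of 19 cases, led by the retinoic acid synthesis gene Aldh1a2 (-3.37 ± 0.16; adjusted p = 0.0195, and adjusted p = 0.195 with an estimated correlation). The leukocyte list rose in 6 of 23 genes, 3 without Wk4 replicate 3 (adjusted p = 0.0105, and adjusted p = 0.492 with an estimated correlation); Cd74 (5.91 ± 0.18) and RT1-Da (5.06 ± 0.18), both of MHC class II antigen presentation, changed most. The matrix list fell in 6 of 25 genes and rose in 1 (adjusted p = 0.00603, and adjusted p = 0.465 with an estimated correlation). The erythroid list fell in 4 of 13 (adjusted p = 0.00552, and adjusted p = 0.201 with an estimated correlation). The early nephron list did not pass, with 5 of 22 genes lower and 1 higher (adjusted p = 0.208). The podocyte list had 2 genes higher and 2 lower of 18, and only 1 higher without E18 replicate 3, Wk4 replicate 2 or Wk4 replicate 3. Its members had a median of -0.02, a mean of -0.05 and a test that pointed up (adjusted p = 0.878).

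The call took in 2529 probe sets between E18 and Wk4, 1302 higher and 1227 lower at Wk4, against a median difference of -0.12 over all probe sets. The share that was higher was 51.5%, but 45.0% with no pseudocount, 43.2% at 2-fold, 49.6% without Wk4 replicate 1 and 61.3% with 4 times the pseudocount, so which direction held more probe sets depended on these choices. Between E13 and Wk4 it took in 4036, with 2123 higher and 1913 lower at Wk4 and a median difference of -0.11. Here the share that was higher was 52.6%, but 48.9% with no pseudocount and 45.8% at 2-fold.

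The comparison of recombined tissue with E13 kidney asked how far the cultured tissue had moved from the earliest stage measured. Col6a3 stood at 75579 ± 1735 in recombined tissue (SD, n = 2) against 671 ± 133 (SD, n = 3), a difference of 6.34 ± 0.17 (limma adjusted p = 6.87e-12). Spp1, which encodes osteopontin, was higher by 6.34 ± 0.19, the calcium-binding protein gene S100g by 6.13 ± 0.37, the myeloid receptor gene Lilrb4 by 5.79 ± 0.27 and the lipid carrier gene Apoe by 5.71 ± 0.21. Hbz (-8.50 ± 0.28), Hbg1 (-8.27 ± 0.27) and Hbe1 (-6.39 ± 0.32) were lowest, followed by Igdcc3 (-3.75 ± 0.30) and Plvap (-3.34 ± 0.33), an endothelial gene.

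Of 23 leukocyte genes, 18 were higher in recombined tissue than at E13 and 0 lower (camera adjusted p = 1.16e-14, and adjusted p = 0.0875 with an estimated correlation). The lysozyme gene Lyz2 differed by 5.55 ± 0.17 and Cd68, a lysosomal protein of macrophages, by 4.60 ± 0.35. The extracellular matrix and myofibroblast list was higher in 16 of 25 genes, Col6a1 (5.35 ± 0.20) among them (adjusted p = 1.16e-16, and adjusted p = 0.0662 with an estimated correlation). Tubular injury genes were higher in 12 of 19 cases, with Spp1 and Gpnmb (5.55 ± 0.19) ahead (adjusted p = 1.23e-09, and adjusted p = 0.0518 with an estimated correlation). Erythroid genes were lower in 8 of 13 cases (adjusted p = 4.81e-08). Of 22 endothelial genes 1 was higher and 6 were lower, or 3 without recombined replicate 1, with Tek, the angiopoietin receptor, at -2.72 ± 0.17 (adjusted p = 0.000219, and adjusted p = 0.295 with an estimated correlation).

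Of 22 early nephron genes, 3 were higher in recombined tissue than at E13 and 0 lower, or 1 lower without recombined replicate 2 (camera adjusted p = 0.501), including Osr2 (3.26 ± 0.32) and Wnt4 (1.95 ± 0.33), the signal for the change of mesenchyme into epithelium. Of 35 proximal tubule genes 2 were higher, Slc13a3 (2.34 ± 0.24) and the aminopeptidase gene Anpep (2.17 ± 0.15), with 0 lower (adjusted p = 0.136). The collecting duct list had 1 gene higher, the steroid-inactivating enzyme gene Hsd11b2 (2.50 ± 0.17), and 1 lower, Slc4a1, of 24, with 2 higher without E13 replicate 2 or 3 (adjusted p = 0.631). Nephron progenitor genes were lower in 4 of 17 cases, in 1 without recombined replicate 1 and in 7 without recombined replicate 2, with Igf2bp1 at -2.53 ± 0.33 (adjusted p = 0.00317, and adjusted p = 0.24 with an estimated correlation). Of 10 ureteric bud tip genes 0 were called by the limma test (camera adjusted p = 0.457), while Emx2 (1.32 ± 0.17) and Gfra1 (-1.22 ± 0.25) differed most and 4 had an adjusted p under 0.05. Emx2 was called without recombined replicate 1 (1.61) and Gfra1 without recombined replicate 2 (-1.82), when 2 genes of the list were lower; 1 was lower without E13 replicate 3. The urothelium list had 1 of 14 genes higher, Upk1b (2.78 ± 0.31; adjusted p = 0.301), and the hypoxia and glycolysis list 4 of 24 (adjusted p = 0.36), among them Adm (2.16 ± 0.54) and Pfkp (1.93 ± 0.34). Without recombined replicate 1, 0 of the 24 were called higher and 2 were called lower, with Adm at 0.85 and Pfkp at 1.04. The median of this list was -0.24, its mean 0.32 and its test pointed up. Cell cycle genes had 0 of 34 called by limma, or 1 lower without recombined replicate 2, and 21 with an adjusted p under 0.05, all with lower values in recombined tissue (adjusted p = 1.95e-07, and adjusted p = 0.28 with an estimated correlation). The loop of Henle and distal tubule list had 2 of 20 genes higher (adjusted p = 0.0436, and adjusted p = 0.23 with an estimated correlation).

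Between recombined tissue and E13, 1098 probe sets were called, 892 higher and 206 lower. The share that was higher was 81.2%, and 68.9% with each array centred on its median.

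Recombined tissue was next set against E18 kidney, the stage of a kidney with nephrons. S100g reached 29899 ± 22370 in recombined tissue (SD, n = 2) against 92.9 ± 81.6 (SD, n = 4), a difference of 6.17 ± 0.35 (limma adjusted p = 3.02e-08). This SE is the one shared over the groups, and the SD of 22370 shows that the recombined arrays themselves lay far apart. Lilrb4 was higher by 5.78 ± 0.25, the macrophage elastase gene Mmp12 by 5.29 ± 0.38, Apoe by 5.24 ± 0.20 and Inhba, an activin subunit gene, by 4.98 ± 0.26. Hbb was lower by a difference of -7.79 ± 0.13, Slc12a1 by -5.39 ± 0.18, Hbe1 by -4.72 ± 0.30, Pdzk1 by -4.62 ± 0.17 and Slc7a13 by -4.21 ± 0.19. Slc12a1, at 115 ± 56.9 in recombined tissue, and Pdzk1 lay below the 40th percentile of both recombined arrays.

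Of 35 proximal tubule genes, 18 were lower in recombined tissue than at E18 and 0 higher (camera adjusted p = 9e-14), Fbp1 (-4.06 ± 0.32), a gluconeogenic enzyme gene, among them. Of 24 collecting duct genes 13 were lower, led by Aqp2 (-3.93 ± 0.42), and 1 was higher (adjusted p = 3.81e-10). Of 22 early nephron genes 1 was higher and 7 were lower, or 4 without recombined replicate 1, with the nephron patterning genes Irx1 (-2.90 ± 0.17) and Irx3 (-2.79 ± 0.17) ahead (adjusted p = 0.00486, and adjusted p = 0.195 with an estimated correlation). Podocyte genes were lower in 3 of 18 cases, Nphs1 (-2.69 ± 0.30) and Rhpn1 (-2.20 ± 0.23) included (adjusted p = 0.00202, and adjusted p = 0.188 with an estimated correlation). Loop of Henle and distal tubule genes were lower in 5 of 20 cases (adjusted p = 0.0021, and adjusted p = 0.0911 with an estimated correlation). Nephron progenitor genes were lower in 3 of 17 cases, and in 1 without recombined replicate 1, among them Bmp7 (-1.85 ± 0.20) and Uncx (-1.86 ± 0.39), the latter not called without recombined replicate 1 (-1.21) and neither called against E18 replicate 4 alone, the single E18 array of set 2 (Bmp7 at -1.51; list adjusted p = 0.00181, and adjusted p = 0.225 with an estimated correlation).

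Leukocyte genes were higher than at E18 in 17 of 23 cases, and in 11 without recombined replicate 1 (camera adjusted p = 7.56e-14, and adjusted p = 0.0911 with an estimated correlation). Cd68 differed by 4.20 ± 0.34 and Cd53 by 3.70 ± 0.27. The matrix list was higher in 9 of 25 genes (adjusted p = 8.27e-14, and adjusted p = 0.0898 with an estimated correlation). The tubular injury list was higher in 7 of 19 and lower in 1, or higher in 4 without recombined replicate 1, with Gpnmb (4.72 ± 0.18) ahead (adjusted p = 5.28e-06, and adjusted p = 0.113 with an estimated correlation). Neural and Schwann genes were higher in 6 of 19 cases, and in 3 against E18 replicate 4 alone, with Stmn2 (3.36 ± 0.37) and the intermediate filament gene Prph (2.56 ± 0.35) ahead (adjusted p = 3.93e-05, and adjusted p = 0.195 with an estimated correlation). The skeletal muscle and cartilage list was higher in 3 of 15 genes, and in 1 without recombined replicate 1, including the muscle genes Myh3 (1.84 ± 0.31) and Acta1 (1.79 ± 0.39; 1.65 and not called against E18 replicate 4 alone), with adjusted p = 0.0436 and adjusted p = 0.24 with an estimated correlation. Of 22 endothelial genes 11 were lower and 1 was higher, with Plvap at -3.23 ± 0.31 and Tek at -2.82 ± 0.16 (adjusted p = 1.86e-06, and adjusted p = 0.225 with an estimated correlation). The lower count was 5, and the higher 0, without recombined replicate 1, and the lower count was 7 against E18 replicate 4 alone. Erythroid genes were lower in 7 of 13 cases (adjusted p = 2.25e-07). Of 34 cell cycle genes limma called 0, and 12 had an adjusted p under 0.05, all with lower values in recombined tissue (camera adjusted p = 0.000433, and adjusted p = 0.465 with an estimated correlation). Ureteric bud tip genes were lower in 2 of 10 cases (adjusted p = 0.00202, and adjusted p = 0.188 with an estimated correlation). The count was 1 without recombined replicate 1, and 4 without E18 replicate 4 or recombined replicate 2. Fatty acid oxidation genes were lower in 2 of 26 (adjusted p = 6.93e-06, and adjusted p = 0.0518 with an estimated correlation). The hypoxia and glycolysis list had a median of -0.10, a mean of -0.04 and a test that pointed up (adjusted p = 0.89). The call took in 995 probe sets against E18, 618 higher and 377 lower in recombined tissue. The share that was higher was 62.1%, and 54.3% both with each array centred on its median and with no pseudocount.

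**Figure D1:**
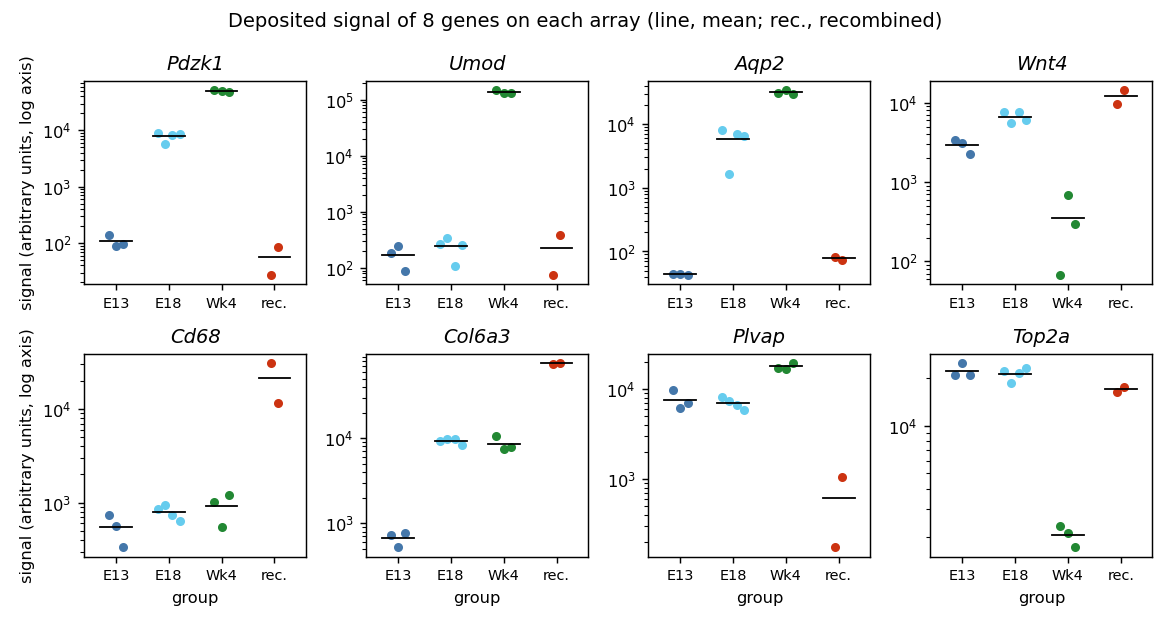
Deposited signal of 8 genes on each of the 12 arrays (points; vertical log axis, arbitrary units), with group means as lines, for E13 (n = 3), E18 (n = 4), Wk4 (n = 3) and recombined tissue (n = 2). On recombined replicates 1 and 2, Pdzk1 stood at 27.3 and 83.9, Umod at 75.7 and 385, Aqp2 at 81.8 and 73.4, Cd68 at 31168 and 11694, and Col6a3 at 74352 and 76806.

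The comparison with the mature kidney at Wk4 had the most calls of the 3 made with recombined tissue. Kap stood at 36.6 ± 13.6 in recombined tissue (SD, n = 2) against 192360 ± 21930 (SD, n = 3), a difference of -9.29 ± 0.17 (limma adjusted p = 9.35e-14). Fbp1 (-8.40 ± 0.33), the peroxisomal oxidase gene Hao2 (-8.40 ± 0.24), Umod (-8.17 ± 0.26) and Sult1c2a (-8.07 ± 0.35) were likewise lower, while Gpnmb (6.66 ± 0.19), the matrix gene Postn (6.37 ± 0.23), Lilrb4 (5.67 ± 0.27) and Igf2 (5.63 ± 0.23) were higher. Xist, the RNA of the inactive X chromosome, had the largest positive difference (7.05 ± 1.59, limma adjusted p = 0.00176). Its signals were 32158 and 50888 on the recombined arrays and 23.5 to 55.8 on the Wk4 arrays. Among E18 arrays it was 52818 on replicate 2 and at most 55.9 on the others. The Y-linked gene Eif2s3y was at 6053 to 7871 on the Wk4 arrays, so these carried male signal alone, while the recombined arrays carried both. Sex thus differed between the groups, and the Xist difference cannot be read as a change made by culture. Effects of sex, for instance on the androgen-regulated Kap, were not separated from those of group.

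Of 35 proximal tubule genes, 34 were lower in recombined tissue than at Wk4 (camera adjusted p = 8.9e-26). The collecting duct list was lower in 21 of 24 genes, with Aqp2 at -6.52 ± 0.44 (adjusted p = 7.88e-12). The loop of Henle and distal tubule list was lower in 17 of 20, with Egf at -7.22 ± 0.23 (adjusted p = 3.6e-10), and the fatty acid oxidation list in 15 of 26, with Acsm2 at -7.49 ± 0.30 (adjusted p = 7.69e-14). Endothelial genes were lower in 10 of 22 cases and higher in 1 (adjusted p = 7.81e-05, and adjusted p = 0.28 with an estimated correlation). Cell cycle genes were higher in 28 of 34 cases, Ccna2 (3.76 ± 0.23) and Ttk (3.73 ± 0.27) ahead (adjusted p = 2.97e-13, and adjusted p = 0.188 with an estimated correlation). Matrix genes were higher in 19 of 25 cases and lower in 1, with Tnc at 4.49 ± 0.32 (adjusted p = 7.55e-08, and adjusted p = 0.195 with an estimated correlation). Renal stroma genes were higher in 10 of 19 and lower in 1, or 0 without recombined replicate 1, with Lum at 4.37 ± 0.22 and Meis1 at 3.85 ± 0.18 (adjusted p = 0.000757, and adjusted p = 0.0851 with an estimated correlation). Neural and Schwann genes were higher in 12 of 19 cases, or 7 without recombined replicate 1, and lower in 1, or 0 without Wk4 replicate 2 (adjusted p = 0.00603, and adjusted p = 0.323 with an estimated correlation).

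In the leukocyte list 15 of 23 genes were higher than at Wk4 and 4 were lower, or 2 without Wk4 replicate 1 or 3, among them Cd74 (-6.13 ± 0.22) and RT1-Da (-5.43 ± 0.22; list adjusted p = 0.00206, and adjusted p = 0.43 with an estimated correlation). Of 22 early nephron genes 3 were higher, with Wnt4 at 4.41 ± 0.33, and 6 were lower, with Irx3 at -3.69 ± 0.18 (adjusted p = 0.441). Of 10 ureteric bud tip genes Ret (2.86 ± 0.19) and Etv4 (2.17 ± 0.46) were higher, the latter not called without recombined replicate 2 (1.49). In the same list 1 was lower, Tfap2b, or 0 without Wk4 replicate 3 (adjusted p = 0.28). Of 17 nephron progenitor genes, 4 were higher, or 7 without recombined replicate 1 and 2 without recombined replicate 2, and 3 were lower, with Bmp7 at -2.43 ± 0.21 and Crym at -2.86 ± 0.22 (adjusted p = 0.186). Of 24 hypoxia and glycolysis genes 1 was higher, P4ha2 (1.96 ± 0.23), and 2 were lower, with Ndrg1 at -4.06 ± 0.22 (adjusted p = 0.277). In this list 7 were lower without recombined replicate 1, while 1 was lower and 2 were higher without recombined replicate 2. The call took in 3435 probe sets, 1781 higher and 1654 lower in recombined tissue, against a median difference of 0.19 over all probe sets. The share that was higher was 51.9%, but 43.0% with each array centred on its median and 47.6% with quantile normalization, so which direction held more probe sets depended on the scaling.

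**Figure D2:**
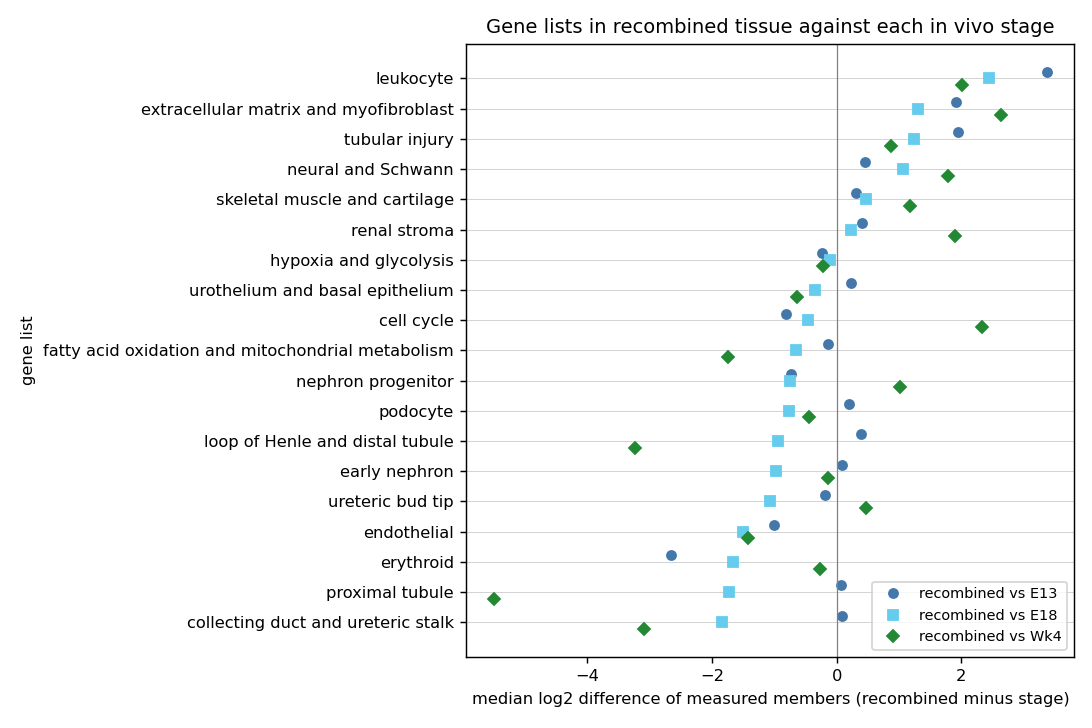
Median log2 difference of the measured members of each of the 19 gene lists (vertical axis) between recombined tissue and E13 (circles), E18 (squares) and Wk4 (diamonds), with 0 as no difference. The leukocyte list lay at 3.37, 2.44 and 2.02, and the proximal tubule list at 0.07, -1.73 and -5.50.

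Placed along the changes from E13 (position 0) to Wk4 (position 1) over the 4036 probe sets called between them, recombined tissue lay at 0.204 ± 0.0221 (SD, n = 2) and E18 kidney at 0.274 ± 0.0113 (SD, n = 4). Both recombined arrays, at 0.219 and 0.188, lay below the lowest E18 array at 0.258. The two-sided exact permutation test gave p = 0.0667, the smallest that its 15 splits allow, so this design cannot pass 0.05. Over the 2123 probe sets higher at Wk4 the recombined position was 0.171 ± 0.0101 against 0.294 ± 0.01 for E18, and over the 1913 lower at Wk4 it was 0.265 ± 0.0448 against 0.237 ± 0.0167. On the changes from E13 to E18, over 529 probe sets, recombined tissue lay at 0.448 ± 0.00717. This slope averages unlike changes. In the 165 probe sets that rose at both steps, the median difference from E13 was 0.34 in recombined tissue and 2.25 at E18. In the 26 that fell at both steps these medians were -1.79 and -1.85. Of the 236 that rose by E18 and then stayed flat, recombined tissue lay above all 3 stages in 51 and below them in 44. Simulated arrays with recombined tissue set equal to E13 gave positions of 0.00885 on the E13 to Wk4 changes and 0.0233 on the E13 to E18 changes, means of 50 draws.

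**Figure D3:**
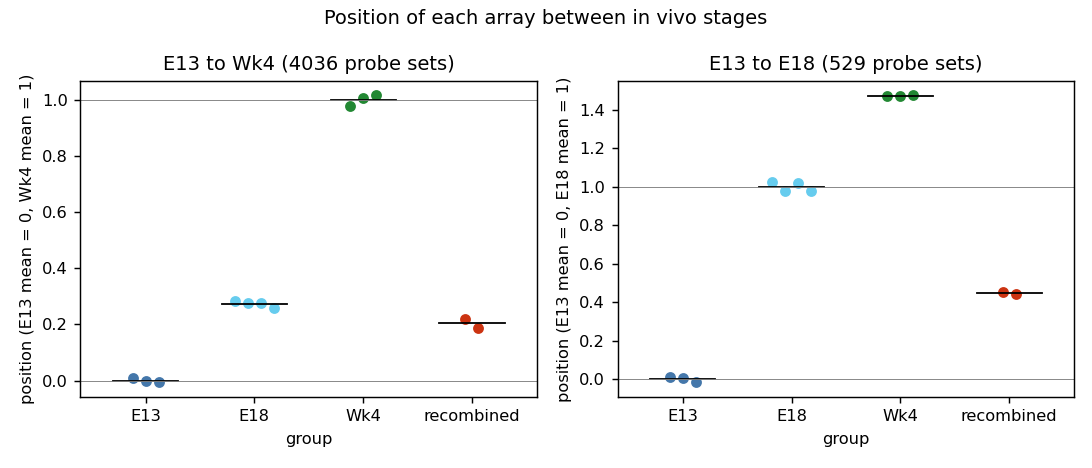
Position of each array (points) along the changes from E13 to Wk4 (left, 4036 probe sets) and from E13 to E18 (right, 529 probe sets), a unitless slope with group means as lines; n = 3, 4, 3 and 2. Recombined arrays lay at 0.219 and 0.188 on the left and at 0.453 and 0.443 on the right.

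Across the 22599 kept probe sets, recombined arrays correlated with the E13 mean at a Pearson r of 0.868 ± 0.0204 (SD, n = 2), with the E18 mean at 0.876 ± 0.0158 and with the Wk4 mean at 0.658 ± 0.00226; the matching Spearman means were 0.853, 0.860 and 0.654. These are correlations across probe sets, which are not independent replicates, and carry no p. The recombined arrays correlated with each other at 0.943, and the E13 mean correlated with the E18 mean at 0.937.

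The study sorted genes with a 3-fold range into 10 patterns, and a similar sorting was made here, which need not match its groups. A 3-fold range over the 4 conditions was found for 5565 probe sets, of which recombined tissue was nearest to E18 in 2711, to E13 in 2078 and to Wk4 in 776. Its mean lay above all 3 stages in 1407 of the 5565 and below them in 891, where the nearest stage need not mean a likeness. The 165 probe sets that rose at both steps had recombined tissue nearest to E13 in 75.2%. The 1165 that were flat from E13 to E18 and fell by Wk4 had it nearest to E18 in 68.6%. In 1105 probe sets neither step was called and recombined tissue had the highest mean of the 4 conditions, and in 463 it had the lowest. With probe sets chosen by the 3 in vivo stages alone, 4326 had a 3-fold range, and recombined tissue was nearest to E18 in 2295, to E13 in 1568 and to Wk4 in 463. Here it lay above all 3 stages in 465 and below them in 594.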

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

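The tests of blood, scaling, macrophages, spike-ins, sex, developmental age and matched random lists below were chosen after the values they bear on, or part of them, had been seen. So were the splits that keep the array sets. The other splits of the samples and the test of the further hypoxia list were set before their results.

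Among the 127 named genes, 13 had an E18 array set apart from the other 3 by a gap that took up most of the range of their values. Chance alone flags about 1 in 20, and a small difference can be flagged when the other arrays lie close together. E18 replicate 2 was low in Aqp2 (1620, the others 6620 to 8106) and Pdzk1 (5753, the others 8340 to 8826), and high in Ldha (79176, the others 40777 to 44737), Tpi1 (67646, the others 35918 to 39684) and Xist (52818, the others at most 55.9). E18 replicate 4 was low in Uncx (6603, the others 14226 to 15477) and Col2a1 (6674, the others 9283 to 9477). It was high in Tfcp2l1 (10350, the others 7620 to 7812) and Cd53 (1233, the others 875 to 922). It was slightly low in Krt7 (4324.9, the others 4822.5 to 4928.1). Kap (22.9, the others 48.7 to 51.3) lay below the added constant of 271 on every E18 array. E18 replicate 1 was high in Fndc3c1 (1613) and low in Crym (5115). Outside the main measurement, the ratio of the 3' to the 5' beta-actin control probe set was 3.87 on recombined replicate 2, above the highest in vivo array (2.56). The same ratio for the GAPDH control was 1.27 there, within the in vivo arrays (1.04 to 1.34).

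The E13 and E18 arrays parted into 2 sets across stages. After the group means were removed, E13 replicate 1 correlated with E18 replicates 1 to 3 at 0.248 or more, and E13 replicates 2 and 3 with E18 replicate 4 at 0.38 or more. In limma, 3398 probe sets differed between the sets at an adjusted p under 0.05, 61 of them by at least 3-fold. The sets were found from these same residuals, so the count describes their extent and does not test that they exist. Sex is argued against by set 1, where E18 replicate 2 had Xist at 52818 and E18 replicates 1 and 3 at most 55.9. The E13 arrays carried both Xist and Y-linked signal, so set 2 does not test sex. The set difference correlated with the change from embryonic kidney to Wk4 at 0.0698 across probe sets. A small age gap between embryos need not follow that change, so age cannot be excluded. On the E13 to Wk4 changes, E13 replicate 1 lay at 0.0087 against -0.0023 and -0.0064 for the others. E18 replicates 1 to 3 lay at 0.277 to 0.284 there, against 0.258 for E18 replicate 4. On the E13 to E18 changes, E18 replicates 2 and 4 both lay at 0.977. Spike-in transcripts, which are added outside the tissue RNA, were higher in set 2 by 0.298 on the log2 scale (two-sided exact permutation p = 0.0286, the smallest that 35 splits allow), so a candidate explanation is a labelling or hybridisation batch. Age, litter and dissection stay open, and no biological explanation beyond sex and age was tested.

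Leukocyte genes were called higher in recombined tissue in 18, 17 (11 without recombined replicate 1) and 15 of 23 cases against E13, E18 and Wk4, and 4 were lower against Wk4 (2 without Wk4 replicate 1 or 3). The erythroid list, as a measure of blood left in the tissue, had a median of -1.67 against E18 and -0.26 against Wk4. It cannot exclude leukocytes carried in with blood, since erythroid cells may be lost over 6 days of culture while leukocytes stay. Scaling of the arrays is argued against by the excess of the leukocyte median over that of all probe sets. This excess was 1.67 on the lower of the 2 recombined arrays and 3.07 on the other. A hypothesis is that macrophages made up more of the cultured tissue. In a macrophage list 14 of 15 genes, or 9 without recombined replicate 1, were higher than at E18 (median 2.75; limma's camera adjusted p = 2.64e-15, and adjusted p = 0.106 with an estimated correlation), 12 of the 15 being in the leukocyte list too, while 0 of 7 lymphocyte genes were called; the lymphocyte median lay 2.59 below the macrophage one (-2.59), with Cd68 at 31168 and 11694 and Adgre1 at 20634 and 7944.5 on recombined replicates 1 and 2. Since 12 of the 15 genes had been seen in the leukocyte list, the macrophage count is mostly not separate support. The others, Mpeg1, Adgre1 and Trem2, were higher than at E18 by 3.89, 4.19 and 2.75. All lymphocyte genes but Lck had mean signals of at most 504 at E18, where the arrays' 40th percentiles were 514 to 585. Their lack of calls is therefore weak evidence. Whether cells multiplied, or each cell changed its expression, was not tested.

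The recombined arrays differed from each other in glycolysis genes: 24 of 24 members of the hypoxia and glycolysis list were higher on replicate 1, with a median of 1.17 against -0.06 for all genes. This median lay at the percentile 100 of 10000 lists matched on expression, which argues against an effect acting alike on genes of a given expression level. A further list of 19 hypoxia-inducible genes, set before its values were seen, had a median of 0.41 at the percentile 99.98. Lower oxygen in the culture of replicate 1 may have contributed, if the 2 arrays came from separate cultures, which the labels do not say. The percentile of 99.98 does not single out oxygen, since the leukocyte and neural lists lay at 100, smooth muscle at 99.99, tubular injury at 99.91, matrix at 99.82 and skeletal muscle and cartilage at 99.77. Members of the hypoxia and glycolysis list moved together within groups (estimated correlation 0.732), which the random lists do not copy. Without culture, Ldha and Tpi1 were also high on E18 replicate 2 (79176 and 67646, the other E18 arrays at most 44737 and 39684). With 1 array on each side there is no replicate check, and an effect of RNA integrity on particular transcripts stays open. The beta-actin ratio of 3.87 on replicate 2 was above the in vivo arrays, while its GAPDH ratio of 1.27 was within them.

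Chance as the source of the stage differences was tested by regrouping the same arrays. For E18 against E13, 1 of 35 splits, the real one, called as many as 529 probe sets, and the highest other called 283. For Wk4 against E18, 1 of 35 called as many as 2529, and the highest other called 1342. A share of 1 in 35 is the smallest that these splits allow. Chance is thus made unlikely but not excluded, and for E18 against E13 only if the array sets are left aside. The replicates may also be technical. For E18 replicate 2 this is argued against by sex, with Xist at 52818 and Eif2s3y at 4.94. The other E18 arrays had Xist at most at 55.9 and Eif2s3y at 12750 or more. Only 12 of the E18 against E13 splits keep the number of arrays of each stage in each set, too few for a share under 0.05: the real one called 529 and the highest other 0. The highest other split of the embryonic arrays moved E18 replicate 4 to the E13 side, and the split by array set called 79. For Wk4 against E13 the 10 splits are too few for a share under 0.05: 1 of 10, the real one, called 4036, and the highest other called 0.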

How the results depend on the processing

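The array sets were chosen after seeing the data; other alternatives were planned. Dim probe sets limit the counts, since the added constant sets their differences. With no pseudocount, calls were 1038 (E18 vs E13), 3990 (Wk4 vs E18), 1732 (recombined vs E13) and 1594 (recombined vs E18), the recombined position between E13 and E18 was 0.461, and correlations with E13, E18 and Wk4 were 0.841, 0.839 and 0.603. With 4 times the pseudocount, calls were 188, 1420, 495 and 418, with 2300 (Wk4 vs E13), 1876 (recombined vs Wk4) and 3053 for the 3-fold range, the position 0.488 and the E18 and Wk4 correlations 0.893 and 0.678. At 2-fold, calls were 1503, 5772, 2839, 2551, 7865, 6885 and 10492 in that order, and the position 0.502. The position was 0.431 with quantile normalization, 0.408 with median centring and 0.437 with array sets as a covariate. The Wk4 correlation was 0.663 with quantile normalization; with no filter correlations were 0.911, 0.918 and 0.781, and with the stricter filter 0.826, 0.832 and 0.501. The cause was not tested beyond what the settings change by construction.

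With 1 array left out, calls ranged from 522 to 589, 2509 to 2699, 918 to 1307, 829 to 1167, 3991 to 4226 and 3412 to 3562 in the same order, and 5520 to 5820 for the 3-fold range. The position between E13 and E18 ranged from 0.416 to 0.479 and that between E13 and Wk4 from 0.188 to 0.219; correlations ranged from 0.860 to 0.886 with E13, 0.871 to 0.891 with E18 and 0.647 to 0.661 with Wk4. A lone recombined array, or the single E13 or E18 array of a set, was assumed to vary like the other groups. Krt14 recombined vs E13, not called (0.50), was 1.03 without recombined replicate 1 and turned to -0.0233 without recombined replicate 2, and the hypoxia and glycolysis list, not called against E18, turned direction with the mean of a gene's probe sets (adjusted p = 0.964).

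Replicate numbers did not pair the samples: 1 of 15 same-number pairs had residuals correlated above 0.1, and 3 of 12 arrays correlated best with their own number. With a replicate block, E18 vs E13 had 582 calls and the position was 0.458; all 57 list calls were kept and 3 were gained. Of 5841 gene results 5728 stayed on their side, 56 lost their call, 56 gained one and 1 reversed. Counts of called genes per list moved more often: of 115 that were above 0, 53 moved by over 1.5 times with 4 times the pseudocount, all downward, 51 at 2-fold, all upward, and 18 without recombined replicate 1, 16 of them downward. Against E18, the loop of Henle and distal tubule genes lower in recombined tissue went from 5 to 1 with 4 times the pseudocount and to 10 at 2-fold, and the endothelial genes from 11 to 4 with 4 times the pseudocount. Ehd3 (E18 vs E13) lost its call when E13 replicate 2 or 3, or E18 replicate 2, 3 or 4, was left out (lowest 1.40).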

Other observations

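The gene groups of the next paragraphs were chosen after their values had been seen, and so were their tests and the leaving out of arrays. Smooth muscle genes were higher in recombined tissue: 11 of 14 against E13, 8 of 14 against E18 and 12 of 14 against Wk4 (camera adjusted p = 2.74e-10 against E18, and adjusted p = 0.106 with an estimated correlation). Actg2, the enteric smooth muscle actin, stood at 46220 ± 24900 (SD, n = 2) against 1108 ± 247 at E18 (SD, n = 4), and the smooth muscle myosin gene Myh11 at 30976 ± 21480 against 1804 ± 414. All 14 stood higher on recombined replicate 1 than on replicate 2 (median 0.54), and without replicate 1 the counts against E13 and E18 were 8 and 7. Smtn, at 3410 against 3868 at E18, was not called (adjusted p = 0.516).

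Imprinted genes differed in whether recombined tissue was near the embryonic level. From E18 to Wk4, 8 of 13 were called lower and 0 higher (camera adjusted p = 0.000934, and adjusted p = 0.28 with an estimated correlation). Igf2 was at 89989 in recombined tissue and 86141 at E18, and H19 at 73950 and 74814, while Cdkn1c was at 24372 and 92507 and Mest at 17163 and 56671. On recombined replicates 1 and 2, Cdkn1c was at 20124 and 28620 and Mest at 11559 and 22768. Meg3 was higher in recombined tissue (15610 against 1469 at E18, difference 3.26). Against Wk4, 10 imprinted genes were higher in recombined tissue and 1, Phlda2, was lower (adjusted p = 0.000238, and adjusted p = 0.225 with an estimated correlation). Of 8 MHC class II genes, 6 rose from E18 to Wk4 (adjusted p = 0.000168, and adjusted p = 0.106 with an estimated correlation) and 5, or 3 without Wk4 replicate 1 or 3, were lower in recombined tissue than at Wk4 (adjusted p = 0.00381, and adjusted p = 0.189 with an estimated correlation).

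Recombined tissue was called higher than all 3 stages in 341 probe sets (217 genes) and lower in 22 (15 genes). Without recombined replicate 1 these were 202 and 31 probe sets, and without recombined replicate 2 they were 351 and 43. Independent lists would share 1.92 and 0.252, and 20 simulated draws with unchanged groups gave 0 of each. The draws gave each probe set independent noise around its E13 mean and held no shared shift of the recombined arrays. A count of 0 was therefore nearly fixed in advance, and it does not test such a shift. The 3 comparisons share the recombined arrays, which raises the overlap above that of independent lists. Genes higher than in every stage included Lilrb4, Gpnmb, Mmp12, Adgre1, Reg3b and S100g, and genes lower included Plvap, Tek, Sox17, Emcn, Hbb and Alas2. The endothelial list did not go one way, since its member Cldn5 was higher than in every stage. Cldn5 stood at 32917 in recombined tissue against 5391 at E13, 9948 at E18 and 2145 at Wk4.

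The sets of genes that set the recombined arrays apart went beyond glycolysis. On replicate 1 the macrophage list was higher by a median of 0.91 and the neural and Schwann list by 0.83, with smooth muscle at 0.54, skeletal muscle and cartilage at 0.35, tubular injury at 0.31 and matrix at 0.24. Lists that were higher on replicate 2 had these medians for replicate 1 minus replicate 2, against -0.06 for all genes: ureteric bud tip -0.62, endothelial -0.47, nephron progenitor -0.44, early nephron -0.39, loop of Henle and distal tubule -0.36, collecting duct -0.32 and cell cycle -0.32. Among 10000 random lists matched on expression, each of the former lay at the percentile 99.77 or above and each of the latter at 1.85 or below. Xist and the Y-linked gene Eif2s3y were both high in E13 and recombined arrays, at 29496 or more and 4099 or more, whereas E18 replicate 2 had Xist at 52818 and Eif2s3y at 4.94, and the other E18 and the Wk4 arrays had high Eif2s3y and Xist at most at 55.9.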
